A study of Mus musculus with 9 samples.

How the data were processed

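Chromatin immunoprecipitation sequencing (ChIP-seq) was carried out by the authors on C57BL/6 mouse embryos at embryonic day 10.5. The labels of all 9 libraries give the otic region of the embryo as the source, whereas the design text of the series speaks of whole embryo and cochlea. The labels of the libraries were followed, and the conflict could not be resolved from the files. The labels list 9 libraries. Brg1, the ATPase of the BAF (SWI/SNF) chromatin remodelling complex encoded by Smarca4, was precipitated in 3 wild-type libraries and in 1 library labelled as Eya1 mutant. H3K27ac, H3K27me3 and Six1 were precipitated in 1 library each, and 1 IgG and 1 genomic input library served as controls. The labels do not state the genotype of the H3K27ac, H3K27me3 and Six1 libraries. Per the labels' protocols, tissue was fixed with formaldehyde, sheared by sonication and made into libraries with a commercial kit.

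The submitters' processing notes name FastQC 0.11.2, Bowtie2 2.2.0, MACS2 2.1.1 and HOMER 4.8.3 and the genome build mm10, without saying which step each served. The deposited files are 5 peak lists, 1 for each group except the controls, and each line gives a chromosome, a start and an end. They hold no score, height, fold enrichment or q-value, so the strength of a peak was not known and peak width stood in for it wherever a rank or a stricter threshold had been planned. The wild-type Brg1 list belongs to 3 libraries, and whether their reads were pooled or their peaks merged is not given in the sources used here. The 2 Brg1 lists differ in form. The smallest gap between neighbouring peaks was -80 bp in wild type, an overlap, and 75 bp in the mutant. The narrowest peaks were 63 bp and 92 bp. Differences between these lists may therefore also reflect how they were made. The threshold of the calls, the control used for each list and the number of reads per library are not given there either, so the depth behind a peak was unknown. The IgG and input libraries were not used here. There was therefore 1 list per group and no spread between embryos could be estimated: genotypes were described side by side, and every interval and test below runs over peaks or genes within these lists, which are not replicates.

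Peak counts were 8574 for wild-type Brg1, 8088 for Eya1-mutant Brg1, 4148 for Six1, 17226 for H3K27ac and 41010 for H3K27me3. A peak was called shared between lists when it overlapped a peak of the other list by 1 bp or more. Shares carry exact (Clopper-Pearson) 95% binomial intervals over peaks, which cover counting error only. The overlap of lists was compared with 1000 placements of the peaks at random on their own chromosome, beyond its first 3 Mb, which are not assembled; the one-sided permutation p from these placements cannot be smaller than 0.000999. The odds that a wild-type Brg1 peak was also in the mutant list were compared by Fisher's exact test (two-sided) and by a Mantel-Haenszel odds ratio over 10 bins of peak width, because wide peaks are found again more often and also overlap other lists more often.

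Gene positions came from a RefSeq table of mouse genes on the same build, with 21887 protein-coding genes on the chromosomes used. The table has no strand, exons or transcription start sites. Distance to the nearer end of a protein-coding gene therefore replaced the planned distance to a transcription start site, a peak was called near a gene end when its midpoint lay within 1 kb of one, and peaks inside genes could not be divided into exonic and intronic. Each peak was assigned to the gene that held its midpoint or, outside genes, to the nearest gene within 100 kb. Motifs were not analysed here, since they need the genome sequence.

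Before the data were examined, 18 gene lists were fixed, with 410 entries and 404 different genes, all of them found in the gene table. They were the Pax-Six-Eya-Dach network, otic placode and vesicle, prosensory and hair cell, otic neuroblast, the Notch, FGF, WNT, and BMP and SHH pathways, BAF complex subunits, cell cycle, hindbrain and neural tube, neural crest and mesenchyme, endothelium and blood, muscle, surface epithelium, the Hox clusters, housekeeping genes, and adult tissue genes with no role in the embryonic head. A few genes stand in more than 1 list. The number of genes of a list with an assigned peak was compared with 10000 random lists of the same size, matched on the size of each gene's territory, which is the part of the genome that would be assigned to it. The two-sided permutation p, from genes redrawn in this way, cannot be smaller than 0.0002, and p-values were adjusted by the Benjamini-Hochberg method over 162 tests of lists and sets of peaks. A later test, chosen after the peaks of the fixed genes had been counted and before its own result was seen, asked how many of the genes with a wild-type Brg1 peak also had a mutant Brg1 peak. It drew, 10000 times, genes with the same number of wild-type Brg1 peaks, the highest numbers being pooled, and a mean peak width in the same coarse class. The distance of the peaks to genes was not matched. The test was run on 19 sets of genes.

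The genes named were also set by a rule written beforehand, with width replacing the score. They were the genes of the Pax-Six-Eya-Dach, prosensory and neuroblast lists with a Six1 peak on a Brg1 peak, at most 12; the genes nearest to the 8 widest wild-type-only, shared and mutant-only Brg1 peaks and to the 8 widest Six1 peaks, each within 100 kb of a gene and counted once per gene, with shared peaks ranked by their width in wild type; from each other list 2 to 4 genes with the widest wild-type Brg1 peaks; and Smarca4, Six1, Eya1, Sox2, Neurog1, Neurod1, Atoh1 and Pax2 whatever they showed. Other genes that are named were chosen after their values had been seen, which is said where they appear.

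The alternatives fixed beforehand were an overlap of at least 50% of the shorter peak, a distance of up to 500 bp, the widest 50% of each list, Brg1 lists of equal length (8088 peaks), placements and bins that kept the distance to the nearest gene end, a limit of 2.5 kb for nearness to a gene end, and assignment limits of 50 and 500 kb. After the data had been seen, 4 were added: leaving out repeat-like clusters, autosomes only, the midpoint of the Brg1 peak in place of the whole peak, and assignment by the nearest gene end. Repeat-like clusters were 4 or more Six1 peaks joined over gaps of up to 5 kb, chromosome Y, and the first 100 kb of assembled sequence of each chromosome. The rule found 25 clusters and took out 231 Six1 peaks (5.57%), 151 wild-type Brg1 peaks and 85 mutant Brg1 peaks; some clusters lie at ordinary genes, among them 6 Six1 peaks beside the Six1 gene.

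Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The code was tested on simulated data. In simulated lists with the size of the 2 Brg1 lists, 25.0% of peaks planted as shared were found as 25.1%. The planted peaks were exact copies, so the recovery of shifted or resized peaks was not checked. With an odds ratio of 3 planted among 8574 peaks and width acting on both sides, the median Mantel-Haenszel estimate was 2.96 and the crude one 3.95. Random lists of 24 genes passed p of 0.05 in 2% of runs, and in 51% when 6 members had been planted near a wild-type Brg1 peak. These lists were drawn from all genes and matched on a random part of gene length in place of territory. The matching on territory was therefore not checked by this simulation. For the later test, the one-sided share of draws was simulated, without adjustment. Sets of 7 genes drawn at random were under 0.05 in 4% of runs, and in 92.5% when 6 members without a mutant peak had been planted. The two-sided, adjusted form was not simulated, so its power is not known.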

Results

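The data described where the chromatin remodeller Brg1 and the homeodomain factor Six1 were found in E10.5 mouse embryos, in tissue labelled as otic region, next to 2 histone marks: H3K27ac, carried by active promoters and enhancers, and H3K27me3, deposited by a Polycomb complex. The question set by the series is how remodellers and lineage factors meet at enhancers when otic ectoderm takes a neurosensory fate. Eya1, the coactivator partner of Six1, was mutated in 1 Brg1 library, and 3 libraries gave Brg1 in wild type. The deposited lists held 8574 Brg1 peaks in wild type (median width 98 bp), 8088 in the Eya1 mutant (138 bp), 4148 Six1 peaks (156 bp), 17226 H3K27ac peaks (358 bp) and 41010 H3K27me3 peaks (473 bp). The 3 wild-type libraries, labelled as replicates, were given as 1 list, and each other group had 1 library, so no spread between replicates could be computed. The lists hold no read counts, and the depth was unknown. Coordinates are those of mm10.

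Of 8 genes fixed beforehand, 7 had a Brg1 peak in the wild-type list and 1 in the Eya1-mutant list. Six1 had 7 wild-type Brg1 peaks and 0 in the mutant. Sox2, needed for prosensory fate, had 4 and 0, and Neurog1, which starts the otic neuroblast programme, had 6 and 1. Eya1, Neurod1 (a neuroblast factor downstream of Neurog1), Atoh1 (the hair cell factor) and Pax2 (a factor of the otic placode) each had 1 wild-type peak and 0 in the mutant. Smarca4, which encodes Brg1 itself, had 0 in both lists. Together the 8 genes held 21 wild-type peaks and 1 mutant peak, and 1 of the 21 had a mutant peak within 500 bp. The 21 peaks were narrow, with a median width of 99 bp. Several, among them the only Neurod1 peak (85 bp), were narrower than any peak of the mutant list (92 bp or more). The 21 include the Atoh1 peak, for which reads from cloned copies of the gene were not excluded.

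Of the 7 genes with a wild-type Brg1 peak, 1 had a mutant peak, against a mean of 4.71 genes in random sets matched on the number and width of their peaks (two-sided permutation p = 0.0038). The test was chosen after the peaks had been seen, and adjusted over the 19 sets of genes it was run on, its p was 0.0722. Atoh1 is among the 7 genes, and the test was not repeated without it. In the complete prosensory and hair cell list, 7 genes had a wild-type peak and 8 a mutant one. Since Eya1 had 1 wild-type Brg1 peak and the lists hold no reads, they could not be used to check the genotype of the mutant library.

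The Six1 gene (ID 20471) lies on chromosome 12, from 73041827 to 73046712. Inside it were 3 wild-type Brg1 peaks, the widest from 73044717 to 73044985, and each of the 3 lay on an H3K27ac peak. The other 4 lay 2.09 to 6.85 kb outside the gene, and the farthest of them was on H3K27ac too. A single H3K27me3 peak of 24245 bp, from 73032410 to 73056654, covered the gene and all 7 Brg1 peaks. The locus also had 9 Six1 peaks, of which 6 formed a cluster between 73049488 and 73052900 that the rule for repeat-like clusters also took. The widest of these, from 73051815 to 73052400, held a wild-type Brg1 peak of 77 bp and no H3K27ac. At Sox2 (ID 20674, chromosome 3, 34649995 to 34652461), 1 Brg1 peak was inside the gene on H3K27ac, at 34650946 to 34651066. A second lay 1.89 kb from the gene, and these, with another 12.9 kb away, stood in an H3K27me3 peak of 38320 bp. The fourth was 89.5 kb away, outside both marks. At Neurog1 (ID 18014, chromosome 13, 56250478 to 56252180), 1 of the 6 wild-type peaks was inside the gene and 1 was 0.116 kb from its end. The only mutant peak, at 56221541 to 56221646, overlapped the wild-type peak farthest from the gene, 28.9 kb away. Over the 8 genes, 19 of the 21 wild-type Brg1 peaks lay on H3K27me3 and 7 on H3K27ac.

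**Figure D1:**
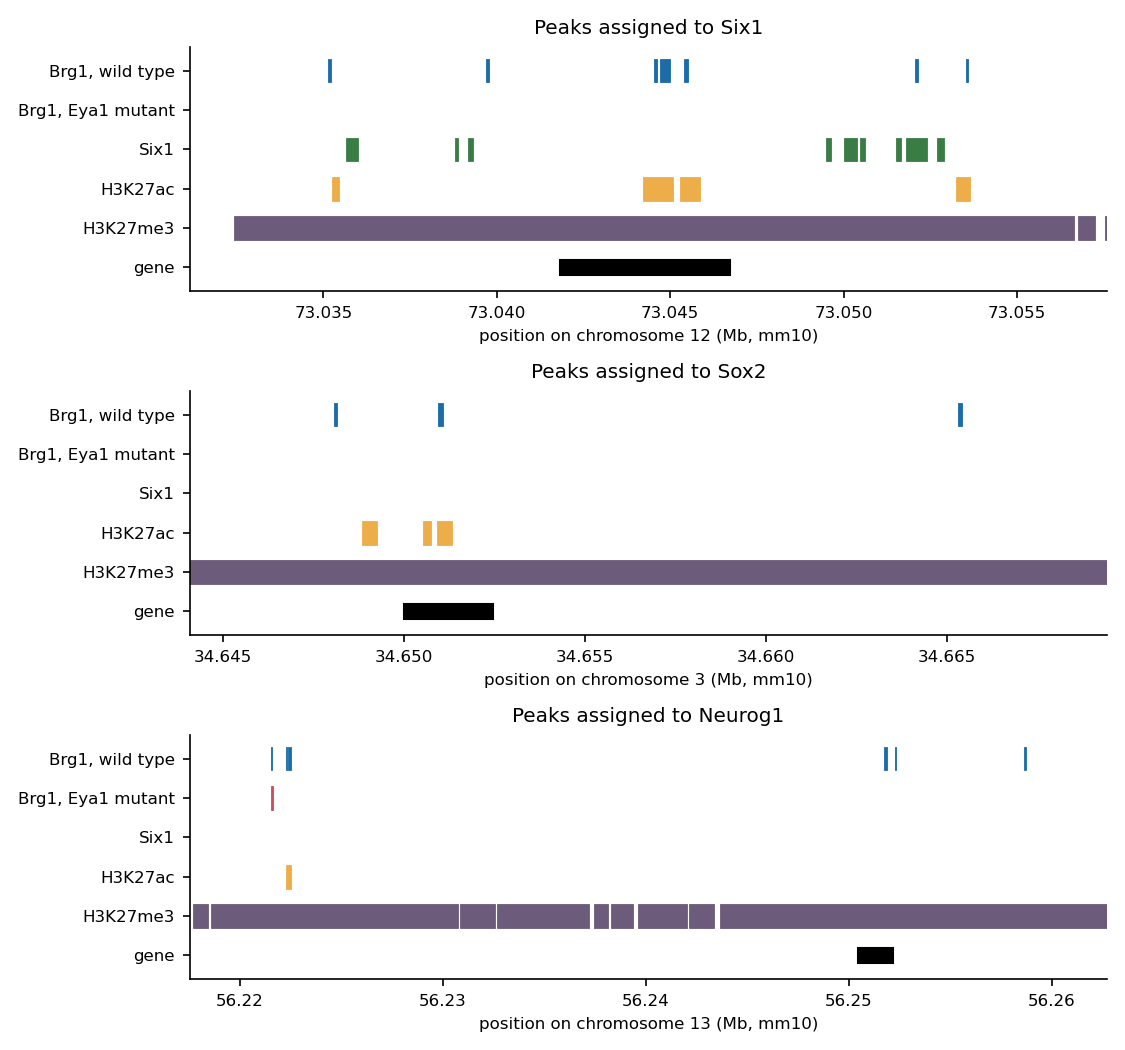
Peaks assigned to Six1, Sox2 and Neurog1, drawn to scale along the chromosome in Mb (mm10), with 1 row for each peak list and the gene body in black; a Brg1 peak 89.5 kb from Sox2 is outside its panel. Wild-type Brg1 peaks were at each gene, and the mutant list held 1 peak, at Neurog1.

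Over the whole genome, 2010 of the 8574 wild-type Brg1 peaks (23.4%, 95% interval 22.5 to 24.4) overlapped a mutant peak, and 1929 of the 8088 mutant peaks (23.9%, 22.9 to 24.8) overlapped a wild-type peak. Random placement gave 7.94 shared peaks, 253-fold fewer (permutation p = 0.000999, the smallest possible). Genes were shared more often than peaks, but this is a looser measure. A gene counts as shared when any peak of each list is assigned to it, wherever the peaks lie. Wild-type peaks were assigned to 3946 genes and mutant peaks to 4755, with 2486 in both (63.0% of the wild-type genes). Independent lists would share 857 if every gene were equally likely to have a peak, so the size of gene territories was not taken into account. The share of wild-type peaks found in the mutant rose from 13.4% in the narrowest of 10 width bins to 45.7% in the widest. Bins 1 to 4, which end at 88 bp, held peaks narrower than any in the mutant list, where the narrowest had 92 bp. Counting peaks within 500 bp of each other raised the shared part of the wild-type list to 41.5%, and placements that kept the distance to genes lowered the excess to 44.04-fold.

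Of the peaks within 100 kb of a protein-coding gene, taken once per gene, the widest of the wild-type list without a mutant peak were at Atoh1, Hspa1a, Meis1, Midn, Sox4, Rcor1, Tra2a and Fbxl14. The Atoh1 peak (chromosome 6, 64729455 to 64730390) was the widest of the wild-type list, at 936 bp, and lay inside the gene on H3K27me3 and without H3K27ac. Meis1 is a homeodomain factor, and its peak of 560 bp carried neither mark, while the peak of 526 bp in Sox4, a factor of neural progenitors, was on H3K27ac. By the same rule, which leaves out wider peaks far from genes, the widest found only in the mutant were at Pou4f3, Man2a1, Tpbg, Homer3, Qpct, Ccr1, Ralgapa1 and Rbm24. Pou4f3, a factor that keeps hair cells alive, had a peak of 924 bp inside the gene (chromosome 18, 42395036 to 42395959), again on H3K27me3 and without H3K27ac. Whether the peaks in Atoh1 and Pou4f3 follow exons could not be examined, and reads from cloned copies of these genes were not excluded. Among shared peaks, ranked by their width in wild type, the widest were nearest to Ly6c2, Mrpl23, Mn1, Zmiz1, Skida1, Tuba1c, Myo1b and Foxp1. Those at Zmiz1, Skida1, Tuba1c, Myo1b and Foxp1 were on H3K27ac, and the one of 765 bp near Ly6c2 was on Six1 and both marks.

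Genes of the BMP and SHH, WNT and Notch pathways were near Brg1 more often than random genes in both genotypes. Of the 22 genes of the BMP and SHH pathways, 19 had a wild-type Brg1 peak and 19 a mutant one, where random lists gave 6.19 and 7.15 (adjusted permutation p = 0.00135 for both). Among them were Ptch1, the SHH receptor, with 7 wild-type and 5 mutant peaks, Id2 with 6 and 4, Id3 with 10 and 9, and Smad6, an inhibitor of BMP signalling, with 8 and 10. Of the 24 WNT genes, 16 had a peak in wild type and 16 in the mutant (adjusted permutation p = 0.00209 and 0.00135), Tcf7l2, Fzd2, Lef1 and Tcf7l1 among them. Of the 16 Notch genes, 11 and 10 had one (adjusted permutation p = 0.00135 and 0.0128), including Notch1 with 7 and 4 peaks, Rbpj with 4 and 0, Lfng with 5 and 4, and Hes1 with 4 and 7. The FGF pathway passed in neither list, with 9 and 11 of 18 genes (adjusted permutation p = 0.152 and 0.0504). The widest wild-type peaks of Spry2 and Fgfr2 overlapped mutant peaks, that of Fgfr1 did not, and that of Dusp6 did but lay in a repeat-like cluster.

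Of the 24 otic neuroblast genes, 12 had a wild-type Brg1 peak, where random lists gave 5.64 (adjusted permutation p = 0.0214), and 7 had a mutant peak, where they gave 6.65 (adjusted permutation p = 1). With the peaks of wild type alone, 7 of the 18 lists were above random. Among them were otic neuroblast, with these 12 genes, and otic placode and vesicle, with 11 of 26 (adjusted permutation p = 0.00665 and 0.0305). The others had lower values: BMP and SHH (17 of 22, 0.00135), cell cycle (12 of 23, 0.00135), WNT (15 of 24, 0.00209), housekeeping (11 of 23, 0.00209) and Notch (9 of 16, 0.0036). With the peaks of the mutant alone, 4 lists were above random and 1 below. Those above were BMP and SHH (18 of 22, adjusted permutation p = 0.00135), WNT (15 of 24, 0.00135), Notch (10 of 16, 0.00209) and BAF (13 of 28, 0.0173). Adult tissue genes were below (0 of 30, 0.0349). The matched draws asked only whether genes with a wild-type peak also had a mutant peak. They ran over genes within 2 lists, left out genes with mutant peaks alone, and are no test between genotypes. Of the 12 otic neuroblast genes, 6 had a mutant peak against 8.29 in the draws, which did not pass (permutation p = 0.219). Of the 12 genes of the Pax-Six-Eya-Dach network, 7 and 4 had a peak (adjusted permutation p = 0.185 and 1), and 2 of the 7 were found in both genotypes against 4.48 in the draws (permutation p = 0.0834). Adjusted over the 19 sets of genes, none of the 18 lists passed the matched draws (lowest adjusted permutation p = 0.369). The lowest unadjusted value belonged to a list that is not otic, hindbrain and neural tube, with 1 of 5 genes kept against 3.45 in the draws (permutation p = 0.0488). In the prosensory and hair cell list the counts were 7 and 8 of 18, and in the otic placode and vesicle list 11 and 9 of 26, none past the threshold. In this last list Irx5 had 10 wild-type and 2 mutant peaks, Prdm16 17 and 8, Msx2 2 and 1, and Sall4 1 and 1.

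Subunits of the BAF complex had Brg1 at 12 of 28 genes in wild type and 17 in the mutant (adjusted permutation p = 0.0368 and 0.00278), and all 12 were among the 17. Arid1a, Arid2, Bcl7a and Smarcd3 were examples. Cell cycle genes numbered 13 and 11 of 23 (adjusted permutation p = 0.00135 and 0.0507), with Ccnd3, Mycn, Cdk4 and Cdkn1a the ones with the widest wild-type peaks. Housekeeping genes, such as Hspa8, Ubc, Ppia and Eef2, numbered 12 and 9 of 23 (adjusted permutation p = 0.00135 and 0.0216).

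Markers of other cells that the dissected region can hold did not pass in either genotype. Neural crest and mesenchyme had 11 wild-type and 13 mutant genes of 28, with Sox5, Prrx1, Tfap2b and Col1a2 in the wild-type list. Hindbrain and neural tube had 5 and 4 of 26 (Irx3, Lmx1b, Nes and Zic2 in wild type), and endothelium and blood 7 and 6 of 22 (Fli1, Erg, Flt1 and Lmo2). Muscle had 3 and 3 of 16 (Mef2c, Msc and Pax7), surface epithelium 5 and 4 of 15 (Epcam, Grhl2, Tfap2c and Cdh1), and the Hox clusters 6 and 7 of 39 (Hoxa3, Hoxa1, Hoxc4 and Hoxa2). Of 30 genes of adult tissues, 2 had a wild-type peak (Slc34a1 and Prl, adjusted permutation p = 0.528) and 0 a mutant one, below the 5.38 of random lists (adjusted p = 0.0123).

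**Figure D2:**
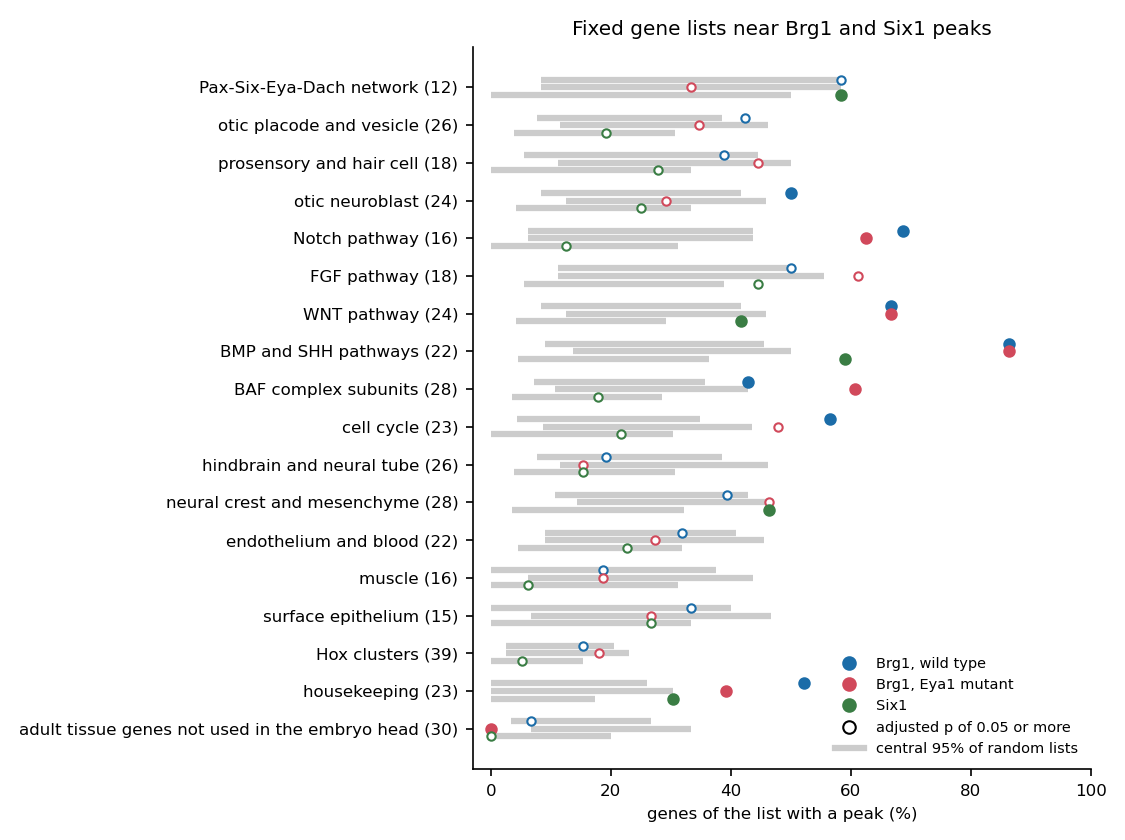
Share of the genes of each fixed list (number of genes in brackets) with a Brg1 peak in wild type or the Eya1 mutant or with a Six1 peak, in percent; grey bars span the central 95% of 10000 random lists, and filled points passed an adjusted p of 0.05. The BMP and SHH list reached 86.4% in both Brg1 lists, and the otic neuroblast list 50% in wild type and 29.2% in the mutant.

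Six1 peaks coincided with Brg1 at a minority of sites, and most carried neither histone mark. Of the 4148 Six1 peaks, 395 (9.52%, 8.65 to 10.46) overlapped a wild-type Brg1 peak and 303 (7.30%, 6.53 to 8.14) a mutant one. Counted on the same Six1 peaks, 186 had Brg1 in both genotypes, 209 in wild type alone, 117 in the mutant alone and 3636 in neither. Both overlaps exceeded random placement, by 88.0-fold and 60.7-fold (permutation p = 0.000999 for each), and 30.4-fold and 15.4-fold when placements kept the distance to genes. The share with wild-type Brg1 was 16.7% for peaks within 500 bp, 6.32% in the widest 50% of each list and 7.28% without repeat-like clusters, where the counts were 126, 159, 110 and 3522.

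Six1 peaks were found near genes of its own network more often than near random genes. Of the 12 genes of the Pax-Six-Eya-Dach network, 7 had a Six1 peak (2.83 in random lists, adjusted permutation p = 0.0434), led by Six1 itself with 9 peaks; Eya1 and Pax2 had 1 each. Six1 was also the only gene of the network, prosensory and neuroblast lists with a Six1 peak on a Brg1 peak. That peak lies in a repeat-like cluster. Without such clusters, 0 of the 12 network genes had a Six1 peak on a wild-type Brg1 peak. Other lists that passed for all Six1 peaks were BMP and SHH with 13 of 22 genes (adjusted permutation p = 0.00135) and neural crest and mesenchyme with 13 of 28 (0.00278). WNT, with 10 of 24 (0.0162), and housekeeping, with 7 of 23 (0.00512), passed as well. In the BMP and SHH list 5 genes had a Six1 peak on a wild-type Brg1 peak, where random lists gave 0.405 (adjusted permutation p = 0.00135); they were Bmpr1b, Smad6, Smad7, Id2 and Gli3, of which Bmpr1b, Smad7 and Gli3 are named after their values were seen. With the widest 50% of each peak list, 3 gene lists passed for Six1 in place of 5.

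With Six1 peaks, the otic neuroblast list had 6 of 24 genes, prosensory and hair cell 5 of 18, otic placode and vesicle 5 of 26, Notch 2 of 16 and FGF 8 of 18, and none of these passed (lowest adjusted permutation p = 0.0582, for FGF). The widest Six1 peaks within 100 kb of a gene, taken once per gene, were nearest to Sfi1, Cspg4b, Gdf15, Sobp, Eef2, Akap6, Tcf19 and Tpsb2. Sobp is linked to inner ear development, and its Six1 peak of 893 bp (chromosome 10, 43002836 to 43003728) was inside the gene with no Brg1 peak and neither mark. Those at Sfi1, Tcf19 and Eef2 belonged to repeat-like clusters; the largest such cluster, at the start of the assembled part of chromosome 9, held 56 Six1 peaks and 45 wild-type Brg1 peaks.

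Wild-type Brg1 peaks with Six1 were found in the mutant list more often than those without it. Of 423 with a Six1 peak, 195 (46.1%) were shared with the mutant, against 1815 of 8151 without (22.3%). The Mantel-Haenszel odds ratio over peak width was 2.81 (2.29 to 3.45), and Fisher's exact test gave p = 1.11e-25. Without repeat-like clusters the odds ratio was 2.34 (1.84 to 2.99), and with a distance of up to 500 bp it was 1.77 (1.53 to 2.06). Brg1 peaks on H3K27ac were also kept more often, 35.3% against 12.7% (odds ratio 3.17, 2.84 to 3.55), and to a smaller degree those on H3K27me3, 30.4% against 21.8% (1.56, 1.38 to 1.76).

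Brg1 peaks that appeared in the mutant alone lay on H3K27me3 more often than those of wild type alone. The mark covered 31.8% of the 6159 mutant-only peaks (30.6 to 32.9) and 17.6% of the 6564 wild-type-only peaks (16.7 to 18.5). Held at equal distance to gene ends, the odds ratio was 2.00 (1.84 to 2.18; crude Fisher p = 1.13e-77). For H3K27ac the shares were 47.8% and 40.1%, and at equal distance the odds ratio was 1.03 (0.957 to 1.11). Shared peaks had the most H3K27ac, 71.4% (69.4 to 73.4). In the complete lists, 47.4% of wild-type and 53.4% of mutant Brg1 peaks were on H3K27ac, and 19.3% and 30.4% on H3K27me3. The direction for H3K27ac was lost in the widest 50% of each list, with 48.6% in wild type and 48.1% in the mutant. The overlaps of the complete wild-type and mutant lists with each mark exceeded random placement, by 9.01-fold or more on the same chromosome and by 3.02-fold or more at a kept distance to genes.

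**Figure D3:**
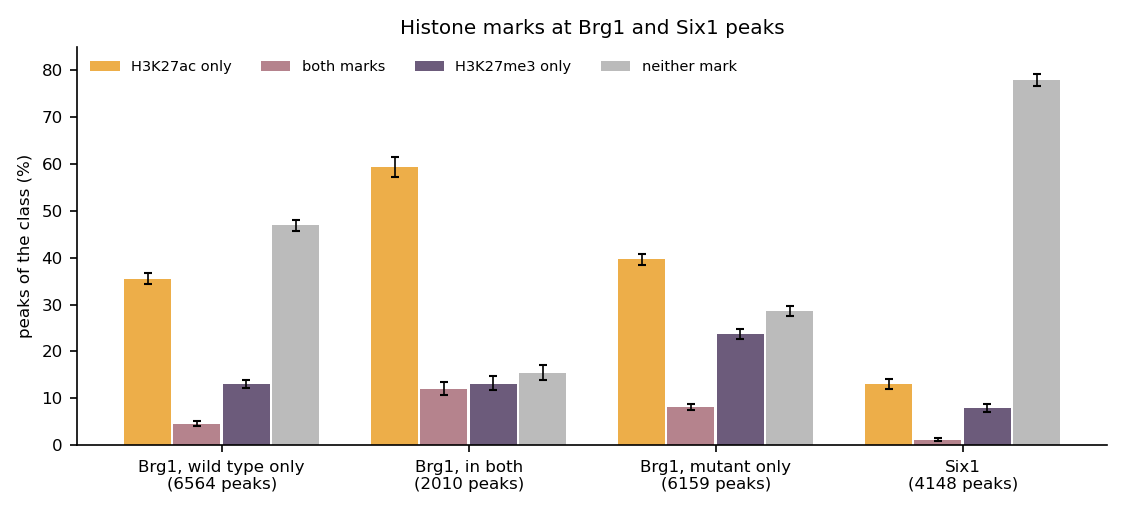
Percent of the peaks of each class that overlapped H3K27ac only, H3K27me3 only, both or neither; error bars are exact 95% binomial intervals over peaks. Mutant-only Brg1 peaks had 23.7% on H3K27me3 only against 13.0% of wild-type-only peaks, and 78.0% of Six1 peaks had neither mark.

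Of the Six1 peaks, 14.1% were on H3K27ac and 9.04% on H3K27me3, and 78.0% (76.7 to 79.2) on neither. Among the 395 with wild-type Brg1, 34.7% (30.0 to 39.6) were on H3K27ac and 19.7% on H3K27me3. The H3K27ac share was above that of all Six1 peaks and below the 47.4% of all wild-type Brg1 peaks. Without repeat-like clusters, 285 of the 395 remained, with 41.8% on H3K27ac. Of the 395, 16.7% lay within 1 kb of a gene end. The genotype of the tissue used for the histone marks and Six1 was not stated in the labels.

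Mutant Brg1 peaks lay closer to genes than wild-type ones. Within 1 kb of an end of a protein-coding gene were 46.6% (45.5 to 47.7) of mutant and 34.0% (33.0 to 35.1) of wild-type peaks, and the median distances were 1.18 and 3.19 kb. Shared peaks lie at the same places in both lists, so by construction the difference can come only from peaks of 1 genotype alone. The share was 47.2% for mutant-only and 45.1% for shared peaks, and wild-type-only peaks departed from both, with 30.7%. Six1 peaks were the farther ones, with 22.9% near a gene end and a median of 15.0 kb. H3K27ac had 54.8% near a gene end and H3K27me3 9.76%. Random placement gave 2.88% to 3.25% for the 5 lists (permutation p = 0.000999 each). With a limit of 2.5 kb, the H3K27me3 share was 22.2%.

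Notch was the only list above random for both H3K27ac and H3K27me3. With H3K27me3 peaks, 11 of the 18 lists were above random, among them otic placode and vesicle with 25 of 26 genes, neural crest and mesenchyme with 27 of 28, hindbrain and neural tube with 25 of 26, WNT with 23 of 24, and otic neuroblast with 21 of 24 (adjusted permutation p = 0.00135 for each). The other lists above random were prosensory and hair cell (15 of 18), surface epithelium (12 of 15), Notch (13 of 16), FGF (15 of 18), endothelium and blood (15 of 22) and muscle (11 of 16). H3K27ac was above random at cell cycle (22 of 23), housekeeping (21 of 23), BAF (23 of 28), Notch (14 of 16) and BMP and SHH genes (18 of 22), and below it at the Hox clusters (4 of 39) and adult tissue genes (3 of 30). Of the H3K27ac peaks, 10.51% (10.06 to 10.98) overlapped H3K27me3, and 3.88% of the H3K27me3 peaks overlapped H3K27ac. This was 4.17-fold above random placement, and 1.22-fold when placements kept the distance to genes (permutation p = 0.000999 for both).

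Chromosome X held 14920 of the 41010 H3K27me3 peaks (36.4%), and 223 of the 17226 H3K27ac peaks (1.29%). H3K27me3 peaks covered 6.51% of its length, against 1.05% to 3.55% of the autosomes.

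**Figure D4:**
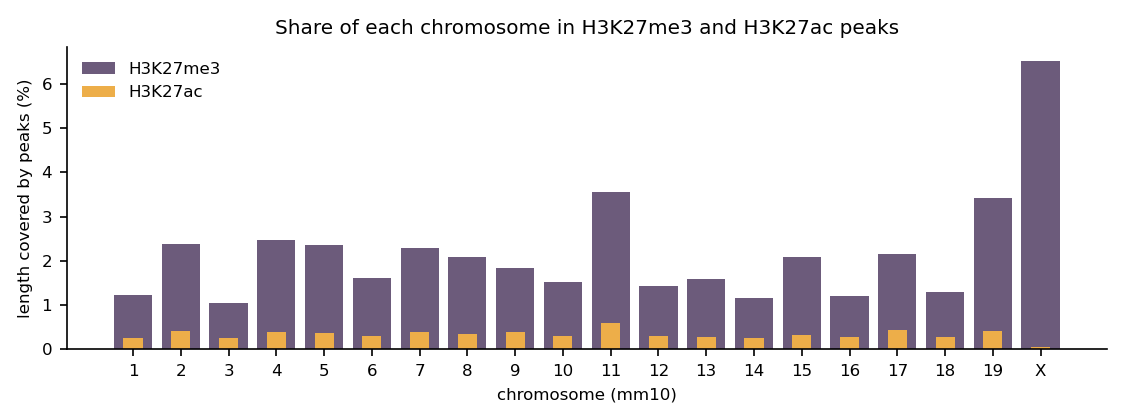
Percent of the length of each chromosome covered by H3K27me3 peaks (wide bars) and H3K27ac peaks (narrow bars). Chromosome X had 6.51% for H3K27me3, above the highest autosome, chromosome 11, with 3.55%, and 0.0489% for H3K27ac, below all autosomes.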

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

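The concentration of H3K27me3 on chromosome X stands outside the comparisons of Brg1 and Six1, which had 0.513% and 1.33% of their peaks there. Of the tests in this part, the one of H3K27ac was chosen after the result was seen, and the median test of escape genes before.

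H3K27me3 peaks on chromosome X made up 36.4% of their list, with 88.9 peaks per Mb against 6.19 to 20.6 on the autosomes. Easier mapping on X would raise H3K27ac as well. Only 1.29% of the H3K27ac peaks were on X, below its 4.41% of protein-coding genes, which argues against easier mapping. An excess of X reads in the H3K27me3 library alone would not raise H3K27ac, which comes from another library, so it stays open. A biological candidate is the Polycomb mark of an inactive X in female embryos, a hypothesis that predicts less H3K27me3 on genes that escape inactivation. The planned test of this decided nothing, since the median coverage was 0 both for 8 escape genes (5 of them with H3K27ac) and for 167 other X-linked genes with H3K27ac (one-sided permutation p = 0.393). Counted afterwards, 2 of the 8 and 83 of the 167 had any H3K27me3 (one-sided Fisher's exact p = 0.158), so the explanation stays open; the sex of the embryos is not stated, and no other biological explanation was tested.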

How the results depend on the processing

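The alternatives of repeat-like clusters, autosomes only, midpoints and nearest gene ends were chosen after the data had been seen. For the 7 tested results (the 4 overlaps against placement and the 3 odds ratios of being kept), all 52 values under the alternatives kept their direction and their side of the threshold; the placement folds ranged from 44.04 to 327 for the Brg1 lists, from 22.2 to 116 and from 12.2 to 74.95 for Six1 with wild-type and mutant Brg1, and from 1.22 to 4.39 for the marks, and the odds ratios from 1.77 to 3.70 by Six1, 2.37 to 4.28 by H3K27ac and 1.44 to 1.74 by H3K27me3. The number of gene lists above random stayed within 1.5 times, except for Six1 in the widest 50%, with 3. Shares moved with the definition of overlap by construction; for the widest 50% and the clusters the cause was not tested. No paired analysis was possible because each group has 1 list and the mutant has 1 library. Leaving out single replicates could not be done, and the 3 alternatives for motifs were not run, as both need data not used here. With no scores and no depth, peaks missing from a list cannot be told from peaks below its threshold.

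An overlap of 50% of the shorter peak gave shared Brg1 peaks of 18.8% (wild type) and 19.3% (mutant), Six1 with Brg1 of 8.58% and 5.93%, H3K27ac on Brg1 of 44.7% and 50.4%, H3K27me3 on mutant Brg1 of 29.3%, H3K27ac on H3K27me3 of 9.20% and the converse of 3.30%. Within 500 bp these were 41.5% and 40.4%, 16.7% and 13.8%, 59.4% and 62.9%, 34.5% (wild type 22.5%), 13.4% and 5.64%. The widest 50% gave 20.8% and 21.2%, 6.32% and 5.40%, 48.6% and 48.1% (the direction between genotypes was lost), H3K27me3 on wild-type Brg1 of 18.0%, 7.83% and 3.12%, and near gene ends 38.7% (wild-type Brg1), 50.3% (mutant), 25.4% (Six1), 68.0% (H3K27ac) and 13.1% (H3K27me3). Brg1 lists of equal length gave 24.4% shared in wild type and 49.6% on H3K27ac. Within 2.5 kb of a gene end were 47.4%, 60.1%, 30.4%, 63.1% and 22.2% of the 5 lists in that order. Without repeat-like clusters, Six1 peaks with Brg1 were 7.28% and 6.03%. On autosomes 13.2% of H3K27me3 peaks were near a gene end and 5.80% overlapped H3K27ac. By midpoint, 44.6% and 50.2% of Brg1 peaks were on H3K27ac and 29.3% of mutant ones on H3K27me3.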

Other observations

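The 10 widest H3K27me3 peaks on autosomes, a choice made after the data had been seen, included peaks at the 4 Hox clusters. The widest were at the Hoxc cluster (179 kb, chromosome 15, 102893292 to 103072763), the Hoxa cluster (152 kb) and the Hoxd cluster (127 kb). Next came Nfix (120 kb) and a part of the Hoxb cluster (117 kb), with Hoxb13 at a separate peak. They were followed by regions at Rhcg, Zic4, Hoxb13, Pax3 and Dmbx1, the last with 58.3 kb. Brg1 was found within several of these, in both genotypes at the Hoxa, Nfix and Hoxb domains, in wild type alone at the Hoxc, Zic4 and Pax3 domains and in the mutant alone at the Hoxd and Dmbx1 domains. The widest H3K27ac peak, of 5260 bp, lay beside Rcor2, a gene of a corepressor in neural progenitors. It was followed by Brd2, Adgrl2, Gm20346, Ptch1, Cdk2ap1, Actg1, Mex3a, Tnrc18 and Mmp14. All 10 had a mutant Brg1 peak, and all except Gm20346 a wild-type one.

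Of the 50 widest wild-type Brg1 peaks, 43 were on H3K27ac and 36 overlapped a mutant peak, so the Atoh1 peak differed from most in both respects. For the 50 widest mutant peaks the numbers were 37 and 33. Whether the peaks inside Atoh1 and Pou4f3 follow their exons was not examined, since exon positions were not used here.

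In what follows, the matched draws for narrow peaks were chosen after the peaks of the fixed genes had been counted but before their own result was seen, and the other tests after their results.

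The loss of Brg1 peaks at the fixed otic genes in the mutant list (21 against 1) has technical and biological candidate explanations. A mutant list with far fewer calls would show the same. It held 8088 peaks against 8574 in wild type, and named 1.21 times as many genes. Mutant peaks lay closer to genes, however, with 18.9% between genes against 25.9% in wild type. The number of genes therefore cannot speak against fewer calls away from genes, which stay open. Narrow peaks near the calling threshold would be lost as often at other genes. The share of matched random sets that kept as few genes was 0.0019, one-sided and unadjusted (two-sided permutation p = 0.0038). The test was chosen after the 21 and 1 peaks had been counted, and it did not pass after adjustment (0.0722). Loss of narrow peaks therefore stays open, and peak heights are unknown. Reads from cloned copies of Atoh1 were not excluded for its peak among the 21. The matched draws were not repeated without Atoh1. Other cells in the mutant tissue may also lower the part of otic cells; of 5 lists of other cell types, 1 had more genes with Brg1 in the mutant (30 genes against 31 over the 5 lists), and with 1 library this cannot be told apart from a role of Eya1 in placing Brg1. The last is the hypothesis the design names, and it was not tested here: the matched draws compare genes within 2 lists, and did not pass after adjustment over all sets (0.0722).

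That no more than 23.4% of wild-type Brg1 peaks overlapped a mutant peak could come from small shifts of position, from weak calls, or from the mutation. Small shifts would bring nearly all peaks within 500 bp, and 41.5% were. Loss of weak peaks near the threshold stays open: 45.7% (42.3 to 49.1) of the widest of 10 bins were kept, but the share rose with width, to 36 of the 50 widest peaks, and width is not a measure of strength. A hypothesis that loss of Eya1 removes Brg1 first from sites with Six1 predicts lower odds of being kept there, and without repeat-like clusters the odds ratio was 2.34 (1.84 to 2.99), but Six1 peaks with Brg1 in wild type alone outnumbered those in the mutant alone by 159 to 110, so it stays open. Depth, pooling of the 3 wild-type libraries and differences between embryos stay open, because the lists hold no reads and the mutant has 1 library.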
